A study of Mus musculus with 108 samples.

How the data were processed

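Single cells of mouse germline stem cell cultures were measured. Germline stem cells (GSCs) are cultured spermatogonial stem cells taken from testes, and germline stem cell-like cells (GSCLCs) are their counterparts grown from pluripotent stem cells through reconstituted testes. Each of the 108 samples was 1 cell, and the titles assigned the cells to 4 culture lines: GSC1 with 30 cells, GSC2 with 24, GSCLC1 with 30 and GSCLC4 with 24. Per the labels' protocols, GSC2 came from separate testes of postnatal day 7, and GSCLC4 from reconstituted testes kept at 34 °C for 3 weeks. All cells were dissociated from culture and amplified by SC3-seq, a single-cell method that reads the 3′ ends of polyadenylated RNA. Cells of 1 line are not replicates, so the culture line was the unit of every test, with 2 lines against 2.

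The authors deposited 1 table of expression signal, given as RPM (read counts scaled to the size of each library), for 26218 genes with Entrez identifiers and symbols and for 92 synthetic spike-in RNAs (ERCC). Per the submitters' processing notes, cutadapt 1.3, TopHat 1.4.1 and Cufflinks 2.2.0 and the mouse build mm10 were used; how reads that map to several places were counted is not given in the sources used here. In the deposited RPM signal the scaling to RPM covers the gene rows and the spike-ins come on top, so the spike-ins were left out of every gene test. Empty spike-in entries (6440) were read as not detected. The most frequent value above 0 in each cell was taken as the worth of 1 read. From it the depth was estimated at a median of 3.45 M reads per cell, with a range of 2.00 M to 6.04 M. Between 85.3% and 92.1% of a cell's values were whole reads within a tolerance of 0.05 read, which was too few to treat the table as counts, so no count model was fitted.

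The value of a gene in a line was the mean RPM over all cells of that line, and tests used log2(mean RPM + 1). A fold change on this scale understates changes of low genes. A line mean can also rest on few of its cells. Genes with a mean of at least 5 RPM in at least 2 of the 4 lines were tested (10526 genes). The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Adjusted p-values and standard errors come from this fit unless another test is named. Gene lists were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the 20 of 24 lists that had at least 5 tested members, and again with an estimated correlation. The test fry was run beside it. Line medians of cell measures were compared with a two-sided exact permutation test, whose smallest possible p with 2 lines against 2 is 0.333. Gene positions are those of the RefSeq annotation of GRCm38.p6, the assembly of mm10, matched by Entrez identifier (24619 of 26218 genes, 93.9%).

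The lists covered undifferentiated and differentiating spermatogonia, germ cell and piRNA pathway genes, methylation-sensitive germline genes, meiosis, spermatids, pluripotency, primordial germ cells, Sertoli cells, Leydig and peritubular cells, fibroblasts and feeder cells, and blood and endothelial cells. Further lists held imprinted genes, the DNA methylation machinery, Hox genes, GDNF and FGF response, S phase, G2 and M phase, immediate early and heat shock genes, p53 response, glycolysis, oxidative phosphorylation, interferon response and MHC class I. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from those marked below as chosen later. The rule named the 12 largest rises and falls among genes past the threshold with at least 20 RPM in the higher type. Where fewer passed, it filled each direction to 12 with genes whose 2 GSCLC line means both lay on 1 side of both GSC line means. It added up to 4 members of each list by size of change and a fixed set of germ cell and pluripotency genes. For lines within a type it named the 5 largest differences per direction among genes with at least 50 RPM in the higher line that were detected in at least 50% of its cells.

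The fit was tested on simulated line values for the 10526 genes, with 200 of them changed, in 20 draws. Values were drawn independently for each gene from a normal distribution around its GSC mean, with the variance that limma had fitted. They held no correlation between genes and no outlying cells, so the rates below may be optimistic for the real data. It recovered 23.8% of genes changed 2-fold, 70.2% of those changed 4-fold and 95.6% of those changed 16-fold, and 6.99% of its calls were false. With 2 lines per type, moderate differences therefore often stayed below the threshold. The alternatives covered the pseudocount, the filter, the summary over cells, scaling, the variance model, left-out cells and left-out lines. By the serial numbers in their titles, the GSC1 cells form 2 runs, from 65 to 80 and from 129 to 150. Each run was also used alone, and the sources used here do not say what separates them. How GSC1 and GSCLC1 were derived is not given in the sources used here. Figures were drawn with matplotlib 3.10.9.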

Results

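The data were single-cell 3′-end expression profiles of cultured mouse cells from 2 lines of germline stem cells (GSC1 and GSC2) and 2 lines of germline stem cell-like cells (GSCLC1 and GSCLC4). A cell had a median of 8865 detected genes (RPM above 0). The line medians were 8791 and 9182 genes in GSC1 and GSC2 and 8607 and 9866 in GSCLC1 and GSCLC4, so that those of the GSCLC lines lay below and above both GSC medians. Estimated depth was lower in both GSCLC lines, with medians of 3.19 M and 3.26 M reads against 3.71 M and 4.30 M (exact permutation test, p = 0.333, the smallest that 2 lines against 2 can give). When each cell was thinned to 2000300 reads, the line medians were 8246, 8547, 8086 and 9347 genes. One GSC1 cell stood apart, with 5748 detected genes, 5.24 median absolute deviations below the median of its line, and 91374 RPM of spike-in RNA against line medians of 33144 to 42622.

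The first comparison asked how closely germline stem cells made from pluripotent cells match those taken from testes. Both expressed core germ cell genes. Dazl and Ddx4, RNA-binding proteins of germ cells, reached 3325 ± 186.4 and 841 ± 108.1 RPM in GSC lines and 3486 ± 50.5 and 971 ± 21.2 RPM in GSCLC lines (mean ± SD, n = 2 lines each). Gfra1 and Ret form the receptor for the growth factor GDNF. Gfra1 had 220 ± 22.8 RPM in GSCs and 260 ± 8.98 RPM in GSCLCs (log2 0.24, adjusted p = 0.769), and Ret had a log2 fold change of 0.33 (adjusted p = 0.768). Against this background 8 of 10526 tested genes differed past the threshold, 6 higher and 2 lower in GSCLCs, among them the Notch target Hey1 and the imprinted gene Mest, which both rose.

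Hey1 (chromosome 3, 8663359 to 8667038) rose from 17.8 ± 5.08 to 90.3 ± 8.98 RPM (log2 2.30 ± 0.36, adjusted p = 0.0475). Mest (chromosome 6, 30733506 to 30748466), which is expressed from the paternal allele, rose from 35.5 ± 11.6 to 135 ± 11.7 RPM (log2 1.93 ± 0.31, adjusted p = 0.0475). Plekhh3 (chromosome 11, 101162679 to 101171378) fell from 80.6 ± 23.3 to 10.6 ± 5.80 RPM (log2 -2.89 ± 0.46, adjusted p = 0.0475). Values of these genes were whole reads in every cell, within the tolerance.

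A further 4 genes past the threshold often had values that were not whole reads, as happens when reads are divided between copies, and their levels are uncertain for that reason. Sfi1 (chromosome 11, 3131850 to 3203347), which encodes a centrosome protein, rose from 18.3 ± 5.77 to 337 ± 27.6 RPM (log2 4.16 ± 0.29, adjusted p = 5.3e-05), and 52.8% of its values above 0 were not whole. LOC434624 (chromosome 10, 130591966 to 130592901), annotated as the ferritin light chain pseudogene Ftl1-ps2, rose from 1.20 ± 0.25 to 112.96 ± 26.0 RPM (log2 5.68 ± 0.51, adjusted p = 5.0e-04), with 88.0% of values not whole. The RNA 1700122H20Rik (chromosome 17, 6895940 to 6901718) rose from 38.2 ± 23.3 to 199 ± 10.2 RPM (log2 2.49 ± 0.37, adjusted p = 0.0442), with 80.6% not whole. LOC100861649, which had no match in the annotation, fell from 1724 ± 420 to 798 ± 113.8 RPM (log2 -1.10 ± 0.17, adjusted p = 0.0475), with 86.1% not whole. The parent gene Ftl1, named after the values were seen, had 288 and 217 RPM in GSC1 and GSC2 and 135 and 194 RPM in GSCLC1 and GSCLC4 (log2 -0.62, adjusted p = 0.499).

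**Figure D1:**
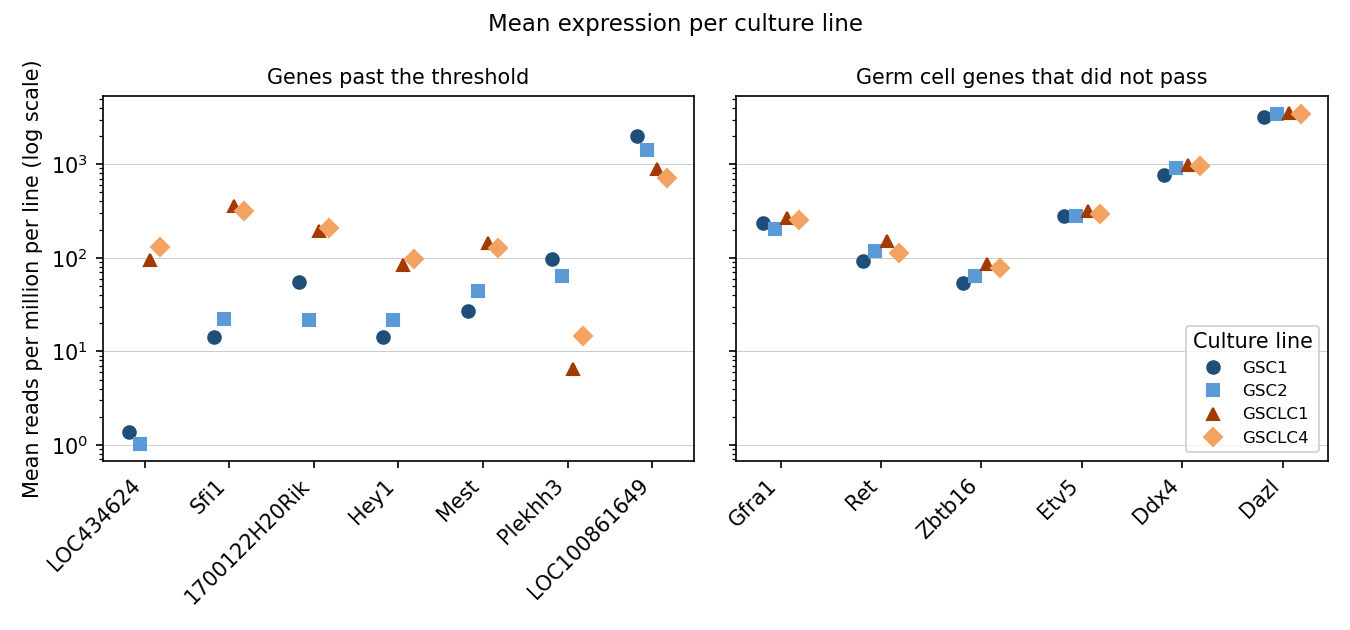
Mean RPM per culture line (log axis) for 7 of the genes past the threshold (left) and 6 germ cell genes that did not pass (right); each symbol is the mean over all cells of 1 line. Hey1 lay at 14.2 and 21.4 RPM in the GSC lines and at 84.0 and 96.7 RPM in the GSCLC lines, while Dazl lay between 3193 and 3521 RPM in all 4.

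The next largest differences separated the types without passing. Among genes above both GSC lines in both GSCLC lines were Hoxa10, Hoxa13 (log2 4.40, adjusted p = 0.0980) and 0610031J06Rik (log2 4.34, adjusted p = 0.0669). Hoxa10 had 0 and 0.010 RPM in GSC1 and GSC2 and 16.8 and 36.9 in GSCLC1 and GSCLC4 (adjusted p = 0.0669). Cells with at least 5 RPM of Hoxa10 made up 13.3% of GSCLC1 and 50% of GSCLC4. For Hoxa13 they made up 13.3% and 54.2%. Slc38a4, a paternally expressed amino acid transporter, had 5.62 and 15.2 RPM in GSC lines and 53.6 and 104 RPM in GSCLC lines (adjusted p = 0.0772), and the log2 fold changes of Sepp1, a selenium transport protein, and of LOC100862013 were 3.22 and 2.85 (adjusted p = 0.211 and 0.428). Genes below both GSC lines included Sfrp2, a secreted Wnt modulator (log2 -2.74, adjusted p = 0.0980), the homeobox gene Prrx2 (log2 -2.46, adjusted p = 0.0980) and the calcium-binding protein S100a6 (log2 -2.51, adjusted p = 0.0669). Cerk, Rhbdl3, Egr3, Lipo1, Car6 and Ramp2 had log2 fold changes from -3.40 to -2.35 with adjusted p of 0.240 to 0.395. Acta2, a smooth muscle actin, had 298 RPM in GSC1, 8.92 in GSC2 and 4.15 and 1.15 in the GSCLC lines (adjusted p = 0.388). The GSC1 cell with few detected genes held 8165 RPM of Acta2 and 9592 RPM of S100a6.

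In the limma test 929 genes had an unadjusted p under 0.05, of which 529 were higher and 400 lower in GSCLCs, and 24 had an adjusted p under 0.1. The 2 types did not overlap in 39.3% of the tested genes, where chance gives 33.3%. Without the GSC1 cell of few detected genes, 10 genes passed, the same 8 together with S100a6 (log2 -1.79, adjusted p = 0.0386) and 0610031J06Rik (log2 4.72, adjusted p = 0.0472). The count rested on single lines, since 5 genes passed without GSC1, 19 without GSC2, 15 without GSCLC1 and 3 without GSCLC4. It was 0 without the variance trend, when 871 genes had an unadjusted p under 0.05, or without a filter on low genes, when 1388 did.

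Gene lists were tested as groups. Across the 24 lists Mest was the 1 member past the threshold over all genes. Camera called the p53 response and glycolysis lists, both lower in GSCLCs, at a preset correlation between genes. Neither passed with an estimated correlation (adjusted p = 0.698 for both), but 0 of the 20 tested lists passed in that run. For glycolysis the estimate was -0.049, below the preset value, yet the unadjusted camera p rose from 0.00303 to 0.0857. Correlation between genes therefore does not explain that loss. For the p53 response the estimate was 0.291 (unadjusted camera p = 0.183). With 4 lines the run cannot decide whether the 2 calls rest on correlated genes. In the p53 response list 11 of 12 tested members had negative log2 fold changes (median -0.70, adjusted p = 0.00192). The median was -0.35 without GSCLC1, -0.36 without GSC2, -1.06 without GSCLC4 and -0.28 with only the GSC1 cells of serial number under 129. No member passed over all genes, and 2 were lower when adjusted over the list alone. These were Ccng1, a cyclin induced by p53 (253 and 273 RPM in GSC lines, 92.3 and 158.2 in GSCLC lines, log2 -1.11), and Pmaip1, which encodes the pro-apoptotic protein Noxa (131.25 and 197 RPM against 81.3 and 68.2, log2 -1.10). Phlda3 had a log2 fold change of -1.23 and Plk2 of -0.86. In the glycolysis list 13 of 17 tested members were negative (median -0.22, adjusted p = 0.0303). Adjusted over the list alone, 2 were lower: Pfkp, a phosphofructokinase (93.3 and 96.0 RPM against 27.6 and 58.1, log2 -1.22), and Pgk1, phosphoglycerate kinase (203 and 188 RPM against 116.5 and 99.5, log2 -0.85). Bnip3, a mitochondrial protein that is not a glycolytic enzyme, had a log2 fold change of -1.96 and Pfkl of -0.83. Directional fry called 0 lists, with 3 at an unadjusted p under 0.05, and fry for change in either direction called 9. These were the undifferentiated spermatogonia, methylation-sensitive germline, pluripotency, primordial germ cell, DNA methylation machinery, Hox, GDNF and FGF response, immediate early and heat shock, and glycolysis lists. Such a call can rest on few members. It does not compare a list with other genes, and 929 of the 10526 tested genes had an unadjusted limma p under 0.05. The DNA methylation machinery list was called with 0 members past the threshold over the list alone and a camera adjusted p of 0.954. The p53 call was lost without GSC2 (adjusted p = 0.0585), without GSCLC1 (0.199) and with only the GSC1 cells of serial number under 129 (0.252), where its adjusted p ranged from 1.1e-05 to 0.252 over all alternatives. The glycolysis call was lost in 8 alternatives, among them without the GSC1 cell of few detected genes (0.0592) and without GSC1, GSC2 or GSCLC4 (0.0688, 0.137 and 0.197), over a range of 0.00204 to 0.205.

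**Figure D2:**
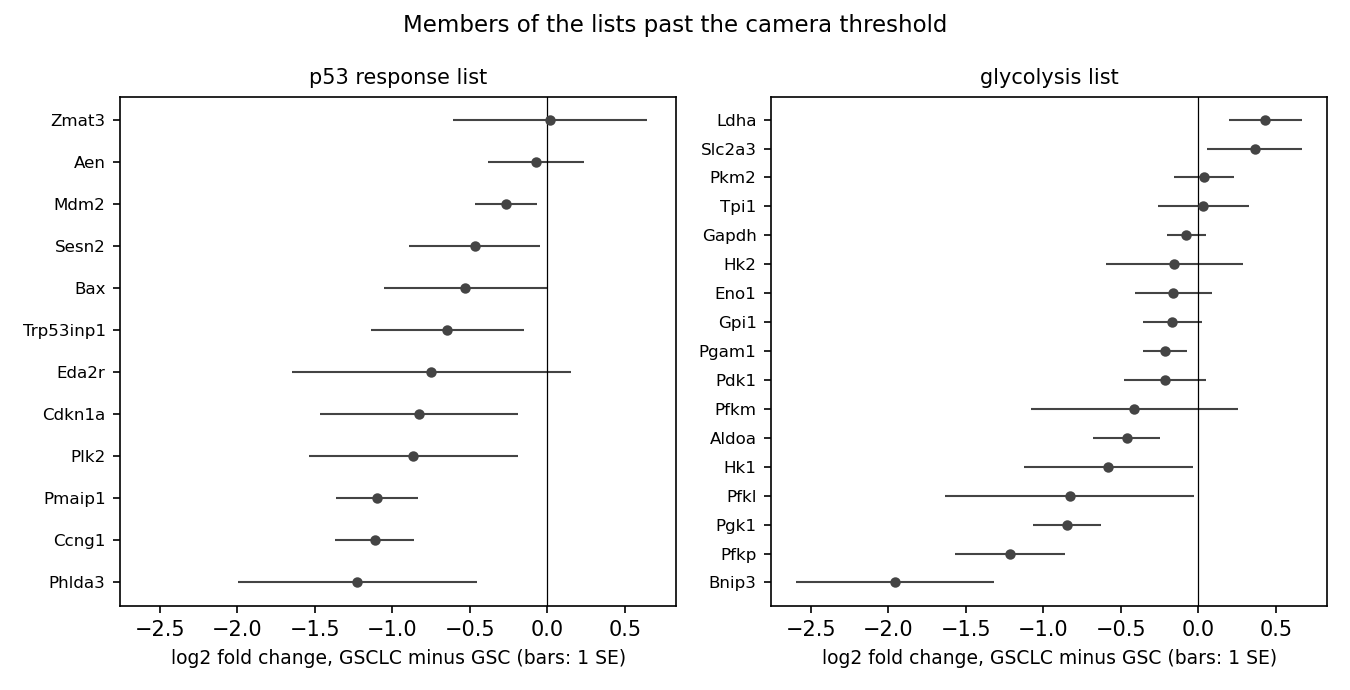
Log2 fold changes, GSCLC minus GSC, of the tested members of the p53 response and glycolysis lists; points are fitted values and bars are 1 SE from limma on 4 line means. Of the p53 response members, 11 of 12 lay below 0, led by Phlda3 at -1.23, and of the glycolysis members 13 of 17, led by Bnip3 at -1.96.

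Spermatogonial genes made up the groups of most direct interest, and no member passed over all genes. In the undifferentiated spermatogonia list 11 of 27 tested members were positive (median -0.28, camera adjusted p = 0.111), and adjusted over the list alone 1 was higher and 5 were lower. Lhx1, a transcription factor induced by GDNF, had 134 and 154.8 RPM in GSC lines and 60.8 and 34.4 in GSCLC lines (log2 -1.63, adjusted p = 0.0980), and Eomes had a log2 fold change of -2.05 without passing. The transcription factors Zbtb16, Etv5 and Id4 had log2 fold changes of 0.48, 0.14 and -0.47 (adjusted p = 0.660, 0.877 and 0.823), and Nanos2 one of -0.43 (0.939). In the GDNF and FGF response list 6 of 19 were positive (median -0.28, camera adjusted p = 0.0845), and 2 were lower over the list alone, Lhx1 and Pou3f1 (log2 -1.32, adjusted p = 0.370). This list shares genes with the undifferentiated spermatogonia list, among them Lhx1, Pou3f1, Etv5 and T, so the results of the 2 lists are not independent. Camera called the GDNF and FGF response list without GSCLC1 (adjusted p = 0.0479) and in 3 more alternatives, and the undifferentiated spermatogonia list with a pseudocount of 10 (0.0442), over ranges of 0.0170 to 0.306 and 0.0442 to 0.365. The mesoderm gene T had 50.0 and 18.9 RPM in GSC lines and 31.6 and 1.92 RPM in GSCLC lines. In the differentiating spermatogonia list 7 of 12 were positive (adjusted p = 0.636), with 0 past the threshold in limma over the list alone. Its members included Sohlh1 (log2 -1.58), Dmrtb1 (1.33), Kit (0.035, adjusted p = 0.995) and Dnmt3b (-0.16, adjusted p = 0.933). Stra8, which marks entry into meiosis, was too low to test at 3.06 and 2.79 RPM against 8.82 and 3.36.

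Camera called neither the germline nor the meiotic lists, while fry for change in either direction called the methylation-sensitive germline genes (adjusted p = 0.0399). In the germ cell and piRNA pathway list 11 of 21 tested members were positive (median 0.069, adjusted p = 0.694) and 0 passed over the list alone. Tex19.1 had a log2 fold change of -1.81 and Tdrd5 of 1.12 (adjusted p = 0.476 and 0.428). Of 28 methylation-sensitive germline genes 20 were positive (median 0.23, adjusted p = 0.534). Dpep3 was lower over the list alone, with 22.4 and 13.7 RPM in GSC lines and 0.0096 and 0 RPM in GSCLC lines (adjusted p = 0.117 over all genes). Of 20 tested meiosis genes 12 were positive (adjusted p = 0.339) and 1 was higher over the list alone. That member was not the cohesin Rec8, which had 9.13 and 4.63 RPM against 15.7 and 32.1 RPM (adjusted p = 0.487 over all genes). Of 18 spermatid genes 4 were tested, and 0 passed over the list alone. Izumo1 had a log2 fold change of 1.58 and Ldhc of 1.01 (adjusted p = 0.595 and 0.726).

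Pluripotency genes were unevenly expressed. Nanog lay between 0 and 0.11 RPM, and Pou5f1 had 5.40 and 4.07 RPM in GSC lines and 0.027 and 0.27 RPM in GSCLC lines, too low to test. Sox2, also a pluripotency factor, had 28.3 and 11.9 RPM in GSC lines and 87.5 and 54.4 RPM in GSCLC lines (log2 1.85, adjusted p = 0.262) and was higher over the list alone. Utf1 had a log2 fold change of 1.98 (adjusted p = 0.525). Of the 10 tested members 4 were positive; the median was -0.12 and the mean 0.36, and camera gave an upward direction (adjusted p = 0.541). In the primordial germ cell list 5 of 8 were positive (adjusted p = 0.339), and 2 were higher over the list alone, Ifitm1 (log2 1.90) and Rhox6 (log2 3.04), each with an adjusted p of 0.395 over all genes. Prdm1 and Dppa3, regulators and markers of early germ cells, had at most 2.00 and 12.9 RPM in any line and were not tested.

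Imprinted and patterning genes held several of the largest differences. In the imprinted gene list 13 of 21 tested members were positive (median 0.53, adjusted p = 0.111), 1 rose over all genes (Mest), and over the list alone 3 were higher and 1 lower. The higher ones were Mest, Slc38a4 and Peg3 (1.02 and 5.21 RPM against 15.6 and 26.5), and the lower one was Gnas (log2 -1.17), which lay outside the naming rule and was chosen after the values were seen. Rasgrf1, which like Mest, Slc38a4 and Peg3 is expressed from the paternal allele, had a log2 fold change of -2.01 (17.6 and 8.45 RPM against 0.012 and 9.66, adjusted p = 0.600). H19, expressed from the maternal allele, had a log2 fold change of -0.34 (adjusted p = 0.919). In alternatives camera called the imprinted gene list without GSC1 (adjusted p = 0.0177), without GSCLC1 (0.0115), with a pseudocount of 10 (0.0442) and with a filter at 20 RPM (0.0280), over a range up to 0.649, and its median was 0.27 without GSC2 or without GSCLC4. In the Hox list 4 of 10 were positive (median -0.44, mean 0.22, adjusted p = 0.541); over the list alone Hoxa10 and Hoxa3 (log2 3.11) were higher and Hoxb2 was lower (log2 -1.89). The Hox median was -1.55 without GSCLC1, where camera called the list (adjusted p = 0.0115), and -0.16 without GSC2, with adjusted p up to 0.946 over the alternatives. Of 18 tested genes of the DNA methylation machinery 6 were positive (adjusted p = 0.954), with 0 past the threshold over the list alone. Dnmt3l, a cofactor of the methyltransferases, had 0.025 and 0 RPM in GSC lines and 7.85 and 6.06 RPM in GSCLC lines (adjusted p = 0.456). It reached 5 RPM in only 6.67% of GSCLC1 and 8.33% of GSCLC4 cells. Tet3 had a log2 fold change of 0.52.

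Markers of other cell types differed widely between lines and cells. The fibroblast and feeder list summed to 2092 RPM in GSC1, 267 in GSC2, 197 in GSCLC1 and 330 in GSCLC4, and 7 tested members had a median log2 fold change of -0.70 (0 positive, adjusted p = 0.110, 0 over the list alone). The adjusted p ranged from 1.6e-08 without GSC2 to 0.960 with only the GSC1 cells of serial number under 129. The GSC1 cell with few detected genes alone held 51019 RPM of this list, 81.3% of the GSC1 sum, against 2716 RPM in the next highest cell and a median of 242. Its germ cell and piRNA pathway genes summed to 1286 RPM against a median of 7176. Vim, an intermediate filament protein, had 686 RPM in GSC1 with that cell and 231 without it, against 71.6 in GSC2 and 35.0 and 58.4 in the GSCLC lines, and Sparc had 86.9 with it and 17.8 without. Of the Sertoli list 4 genes were tested, all positive, and Wt1 (3.94 and 0.55 RPM against 11.3 and 25.8) was higher over the list alone. Wt1 reached 5 RPM in 16.7% of GSCLC1 and 50% of GSCLC4 cells, against 10% of GSC1 and 4.17% of GSC2 cells. Aard had a log2 fold change of 2.01. Of the Leydig and peritubular list 3 were tested, all negative, with Acta2 lower over the list alone and Pdgfra at -1.86. The same GSC1 cell raised the GSC1 mean of Acta2 from 27.2 to 298 RPM, and without it the log2 fold change of Acta2 was -2.33 where it had been -4.04. Of the blood and endothelial list only Kdr was tested (log2 0.032, adjusted p = 0.996).

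Camera on all cells and lines called none of the remaining lists, while fry for change in either direction called the immediate early and heat shock list (adjusted p = 0.0399). S phase genes were positive in 12 of 23 (adjusted p = 0.813), with Tipin at a log2 fold change of 0.42 and Cdc6 at 0.40. G2 and M phase genes were positive in 15 of 24 (adjusted p = 0.534), with Plk1 at 0.87 and Birc5 at 0.52. Of 13 immediate early and heat shock genes 6 were positive (median -0.27, adjusted p = 0.0845), with Zfp36 at -1.14 and Hspa1a at -1.29. Camera called that list without GSCLC1 (adjusted p = 0.0285, range up to 0.417), and its median was -0.021 without GSC1. None of these 3 lists had a member past the threshold in limma over the list alone. Of 26 oxidative phosphorylation genes 16 were positive (adjusted p = 0.694), with the median at 0.054 and the mean at -0.015; Cox8a, a subunit of cytochrome c oxidase, was lower over the list alone (1026 and 887 RPM against 628 and 456, adjusted p = 0.146) and Sdha had a log2 fold change of 0.45. Of 10 interferon response genes 5 were positive (adjusted p = 0.544); Ifi27l1 was higher over the list alone (28.4 and 24.8 RPM against 52.5 and 85.5), and Dhx58 and Stat2 had log2 fold changes of -2.35 and 1.34. Of 9 MHC class I genes 4 were positive (median -0.10, mean 0.020, adjusted p = 0.541); the proteasome activator Psme2 was lower over the list alone (463 and 546 RPM against 317 and 307), and Tap1 had a log2 fold change of 0.74.

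The second comparison set the distance between types against the distance between lines of 1 type. The median absolute log2 difference over the tested genes was 0.37 between GSC1 and GSC2 and 0.38 between GSCLC1 and GSCLC4. Between types it ran from 0.38 (GSC2 and GSCLC1) to 0.43 (GSC1 and GSCLC4). The mean over pairs between types exceeded that within types by 0.022, about the spread of the 4 pairs between types (SD 0.019). Genes that differed at least 2-fold numbered 1533 and 1534 within types and 1693 to 1918 between them. Pearson's r across genes, which are not independent, was 0.914 and 0.919 within types and 0.889 to 0.906 between them.

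Within the types, single lines differed in particular genes, with 1 line on each side and no test. GSC1 exceeded GSC2 in Acta2, Spp1, Timp1, Tpm4 and Vim, genes of matrix and cytoskeleton, by log2 differences of 4.92, 4.59, 3.95, 3.45 and 3.24. Without the GSC1 cell of few detected genes these became 1.51, -0.53, 1.10, 2.17 and 1.68, so that cell carried much of the first set and reversed Spp1. GSC2 exceeded GSC1 in Tmem170b (52.3 against 5.41 RPM, log2 3.05), Lrig3 (2.39), 5730419I09Rik (2.24), Sfrp2 (327 against 72.7 RPM, log2 2.15) and Ugt8a (1.91), and these moved by less than 0.05 without that cell. GSCLC1 exceeded GSCLC4 in the iron carrier transferrin, Trf (86.9 against 4.46 RPM, log2 4.01), in Tcf15 (log2 2.56), 0610012G03Rik (2.41), the mitochondrial enzyme Echs1 (2.36) and 2810407C02Rik (2.09). GSCLC4 exceeded GSCLC1 in the receptor gene Erbb3 (58.5 against 8.79 RPM, log2 2.60), Asph (2.52), the cell cycle inhibitor Cdkn1a (54.2 against 10.1 RPM, log2 2.32), Exd1 (2.10) and 1810019J16Rik (2.03).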

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

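The leaving out of cells in the distances between lines and within types was added after the data were seen; all other alternatives were planned, and the 85 genes followed through them (of each list the 2 largest changes, 4 for called lists, and members past the threshold over the list alone, and Rasgrf1) were picked after the values were seen. Limma's main count was 8 genes. The count was 3 with a pseudocount of 0.1 and 14 with 10; 2 with a filter at 1 RPM, 23 at 20 RPM and 0 without one (1388 at an unadjusted p under 0.05); 22 with the mean of log2 values and 2 with the trimmed mean; 3, all higher, after centring on the median; 0 without the variance trend (871 at an unadjusted p under 0.05); 2 with GSC1 cells of serial number 129 and above and 4 with those under 129. Leaving out 1 line gave 3 to 19 genes and 1 to 5 lists, the lone line being assumed to vary like the others. The wider filters test more genes and the GSC1 subsets hold fewer cells, but the cause of the changed counts was not tested for any setting. The mean of log2 values moved the median of all genes to 0.19 from 0.039. Over the 18 lists without a main call, 34 of 320 medians in the alternatives had the other sign than the main one. The largest of them in absolute size was 0.44, for the pluripotency list with the mean of log2 values, where the main median was -0.12. The 2 called lists became 6 with a pseudocount of 10 and 1 with the trimmed mean, without the cell of few detected genes, or with GSC1 cells of serial number 129 and above; the cause was not tested. Of the 18 other lists 6 passed in at least 1 alternative. Sfi1 passed in 16 of 18 alternatives, LOC434624 in 14 of 16, 1700122H20Rik in 9 of 18, Hey1 and LOC100861649 in 7, Mest and Plekhh3 in 6, with no change of direction. The excess of distances between types over those within (0.022) kept its direction in the 5 alternatives run for it. For detected genes the mean of the line medians was higher by 250 in GSCLC lines and stayed higher in 2 alternatives. It does not show a difference shared by the type, since GSCLC1 had the lowest line median (8607) and GSCLC4 the highest (9866).

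Genes that had not passed changed sign as follows, with log2 fold changes; the cause was not tested. Kit became -0.0064 with a pseudocount of 10, -0.10 with the mean of log2 values and -0.020 with scaling by trimmed means of log ratios, where Kdr became -0.019. Hspa1a became 0.23 with the trimmed mean. With GSC1 cells of serial number 129 and above Nanos2 became 0.34. With those under 129 Kdr became -0.48, Cdc6 -0.10, Hspa1a 0.21, Plk2 0.34, Id4 0.22, Etv5 -0.034, Dazl -0.052, Kit -0.18 and H19 0.017. Without GSC1 Kdr became -0.45, Tet3 -0.27, Cdc6 -0.061, Birc5 -0.17, Tap1 -0.46, Kit -0.72 and H19 0.46. Without GSCLC1 Dnmt3b became 0.18, and without GSCLC4 Kdr became -0.24, T 0.031 and Kit -0.45. The far ends over left-out lines were 0.51 for Kdr, 1.32 for Tet3, 0.85 for Cdc6, 1.22 for Birc5, 0.79 for Kit and -1.15 for H19 (without GSC2), 1.19 for Tap1 and -3.45 for T (without GSCLC1), and -0.51 for Dnmt3b (without GSCLC4). Spp1, higher in GSC1 than in GSC2, became -0.53 without the cell of few detected genes. No paired analysis was run because the labels do not pair GSC lines with GSCLC lines. The planned edgeR and DESeq2 fits were not run because the values are not whole reads throughout. Depth may limit genes near 5 RPM, which was not tested.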

Other observations

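Every test and every group or gene first named in this part was chosen after the result was seen. A group of related genes not described so far is the Fthl17 cluster on the X chromosome, ferritin heavy chain-like genes that lie between 8962134 and 9063822. All 6 detected members were lower in both GSCLC lines than in both GSC lines. Their summed level was 377 and 344 RPM in GSC1 and GSC2 and 107.2 and 180 RPM in GSCLC1 and GSCLC4 (log2 -1.37). The sum is not affected by reads divided within the family, which matters because 85.3% to 94.2% of the values above 0 of single members were not whole reads. Gm14511 (Fthl17c) had the highest level, with 154 and 152.9 RPM against 45.9 and 61.6 RPM (adjusted p = 0.0669), and no member passed the threshold. Lgals1, a galectin, had 806 and 341 RPM in the GSC lines and 74.3 and 185.2 RPM in the GSCLC lines (log2 -2.15, adjusted p = 0.0980, and -1.86, adjusted p = 0.0856, without the GSC1 cell of few detected genes).

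Genes on the distal part of chromosome 6, from 80 Mb to its end, were higher in GSCLC4 than in the other lines, with a median log2 difference of 0.54 over 273 tested genes against 0.15 over the 202 genes before that point. That border was chosen after the values were seen and the bins of 10 Mb do not fall cleanly on either side of it, with GSCLC4 at 0.70 from 10 to 20 Mb (14 genes), 0.43 from 50 to 60 Mb (34 genes) and 0.22 from 100 to 110 Mb (14 genes). GSCLC4 was the highest of the 4 lines in 64.8% of the distal genes, in 51.2% of all chromosome 6 genes and in 30.2% of genes on the other chromosomes. That argues against a few abundant genes. The median over all of chromosome 6 was 0.36, and the highest on another chromosome was 0.19, on X. Because the distal part was picked for its high values, this cannot exclude a contribution from the greater number of genes detected in these cells. All 24 GSCLC4 cells drew a larger share of their RPM from distal chromosome 6 (3.14% to 3.98%, genes under 500 RPM) than any GSC cell (at most 3.00%). The ratio of the GSCLC4 median to that of all other cells, GSCLC1 included, was 1.36 distally and 1.11 proximally. Of 30 GSCLC1 cells 4 also exceeded every GSC cell distally. Proximally 2 of these (3.08% and 2.82%) and 4 GSCLC4 cells exceeded every GSC cell (at most 2.22%). A candidate explanation is an extra copy of chromosome 6 or of parts of it in the GSCLC4 culture, where 3 copies to 2 would give a ratio of 1.5; its extent stays open, DNA was not analysed here, and with a single line the derivation of GSCLC4 stays open as an untested alternative.

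Among the 8 genes past the threshold, 4 belonged to the 537 tested genes (5.10%) in which at least 50% of the values above 0 were not whole reads. For LOC434624 the summed RPM of Ftl1 and this pseudogene differed by only 0.12 on the log2 scale between the types (290 and 218 RPM in GSC lines, 230 and 326 in GSCLC lines), so its rise may reflect reads of Ftl1 assigned differently in the 2 types, as through a sequence variant, which was not tested. For Sfi1, 1700122H20Rik and LOC100861649, where at least 52.8% of the values were not whole, shared reads and a change of the gene itself cannot be told apart, because the other copies were not identified. For Hey1, Mest and Plekhh3 0% of the values were not whole, which argues against shared reads, and a difference between the cell types stays open for them as a hypothesis. Among the 537 genes 8.19% had an unadjusted p under 0.05, against 8.86% of the others.

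The fibroblast list had a negative median in the comparison of GSCLC with GSC lines without being called, and S100a6 was below both GSC lines in both GSCLC lines. The 1 GSC1 cell with few detected genes could account for part of the first. Without it the median log2 difference of the list was -0.42 over 5 tested members, where it had been -0.70 over 7. These medians therefore cover different sets. Without the cell the list sum in GSC1 fell to 405 RPM and the camera adjusted p was 0.760. The median was 0.15 with the mean of log2 values, 0.012 with the trimmed mean and -0.081 without GSC1. It was -3.17 without GSC2, -0.84 with a pseudocount of 10 (camera adjusted p = 0.00892) and -1.27 over 16 members without a filter (0.0300). These last settings all kept that cell, so they cannot show a difference apart from it. Whether the list differs otherwise stays open. For S100a6 the cell is not the whole cause, since the log2 difference was still -1.79 without it and then passed the threshold. No biological explanation was tested for this pattern.

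With 4 lines there are 3 ways to form pairs, too few for a share under 0.05. The real pairing gave 8 genes past the threshold, more than in any other (at most 0 with limma), and 1 of the 3 pairings reached 8. The others had 400 and 292 genes at an unadjusted p under 0.05.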
